A study of Mus musculus with 3 samples.

How the data were processed

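Hypothalami of 8-week-old male mice were dissected, digested with collagenase II and dissociated mechanically, and cells were captured with the 10x Genomics 3' kit (version 3 chemistry), per the labels. The analysis used 3 libraries, 1 each for PF, HS and QS. The deposited values are UMI counts per gene and cell barcode, in matrices that hold 32285 genes and already leave out most empty droplets, since every barcode has at least 500 UMIs. The counts were made by the authors with Cell Ranger against the mm10 mouse genome. The version is 5.0.0 per the submitters' processing notes, which also name Seurat 3.1.2, while the file headers give 7.0.1. Whether intronic reads were counted, the number of mice per library, the time of day of collection and the length of recovery are not given in the sources used here. Raw reads were not used here, and the submitter states that those of QS are missing through file corruption.

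The libraries held 12836 (PF), 12510 (HS) and 11720 (QS) barcodes. Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs, which removed 194, 208 and 211. Doublets were called per library with Scrublet as run in Scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes, and 800, 733 and 737 barcodes were removed at its own threshold (6.33%, 5.96% and 6.40%, where 10.3%, 10% and 9.38% were expected). The 34183 kept cells had medians of 2659.5, 2709 and 2644 genes and of 2.97%, 2.89% and 2.65% mitochondrial UMIs.

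The 3 libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries (Seurat flavour in Scanpy), and 30 principal components and 15 neighbours went into Leiden clustering at resolution 1 with seed 0 (leidenalg 0.10.2), which gave 37 clusters. Clusters were named from marker lists written before the data were examined. A name needed at least 3 markers detected in at least 25% of the cluster's cells at 4 times the CPM of the median cluster, a second class whose score stayed within 60% of the best, and no other class with more markers among the 10 leading genes. A cluster of very low UMI counts also needed a marker among those genes. These thresholds were revised after the clusters had been seen, when haemoglobin RNA had led to erythroid names. Names carry "-like" because they rest on RNA alone, and 3 clusters stayed unnamed. The other software was Python 3.11.15, AnnData 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9.

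Apart from the naming thresholds and the choices named further on as later ones, the results, thresholds, gene lists and most alternatives were chosen before the data were examined. Shares of cells carry exact Clopper-Pearson 95% intervals, and ratios of shares and of CPM carry exact conditional binomial 95% intervals. Within each class, UMIs were summed per library and given as CPM of the class sum, for 7 classes with at least 200 cells in every library. HS was compared with PF, QS with PF and QS with HS. Because each group had 1 library and cells are not replicates, no test was made and no p-value is given. A list median is the median log2 ratio of CPM over members with at least 30 UMIs in the 2 libraries together, given where at least 3 members were measured. Its 95% interval comes from 200 Poisson redraws of the counts. It was also ranked among 10000 random lists of the same size matched on mean expression (each member drawn from the 100 nearest genes), which describes these libraries and is not a test. Where the text gives a value over classes, it is the median of the 7 class values.

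The genes named by rank follow a rule set beforehand. For each comparison and each of the 6 largest classes they are the 2 highest and 2 lowest ratios among genes with at least 50 CPM and 30 UMIs in the library with more and at least 1 UMI in the other. Their CPM also had to reach 20% of the highest CPM of any class, to keep out free RNA. Mitochondrial, ribosomal protein, haemoglobin and provisional Gm and Rik genes were left out. Genes with a ratio of at least 1.5 the same way in all 6 classes, with at least 50 CPM in the library with more and 1 UMI in the other and the same kinds left out, were to be named as well, and there were 0. Some genes that the rule picks are not reported here. From each list up to 4 members with the largest ratios were open to naming. Other genes named were chosen after seeing the data: Gh, the glucocorticoid members shown for classes in which they did not differ, and markers of clusters. Ddit3, Clec7a and Aldoa were left out of their lists because their symbols belong to several gene identifiers. Ifit3 and Ifit3b lie side by side and are near-identical, as are Hspa1a and Hspa1b, so the division of counts within each pair is uncertain. Coordinates are those of GENCODE M21 on mm10 (GRCm38), 1-based and matched by Ensembl identifier.

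Carry-over from HS to QS used PF cells split at random into 2 equal parts within each class. Pairs of a gene and a class with a ratio of at least 2 and an interval excluding 1 in HS against the first part were chosen, and the share with a ratio of at least 1.5 the same way in QS against the second part was counted. The same steps were run on simulated libraries with no difference. The calls were tested on simulated data with known ratios at the depth of each class. Both libraries were drawn as Poisson counts from 1 pooled profile, so the simulation held counting error only. It does not show how calls and intervals behave with differences between cells, clusters or libraries. A ratio of 1.5 was called in 49.4%, 44.5% and 50.8% of genes (HS/PF, QS/PF and QS/HS), as its expected value lies on the threshold, and a ratio of 2 in 100%, 100% and 99.8%. Of 25547, 25497 and 25506 gene and class pairs with no difference, 2, 1 and 3 were called. In the classes the intervals held the true ratio in 94.47% to 95.77% of genes, and simulated lists at a ratio of 1.5 (0.585 on the log2 scale) gave medians of 0.558 to 0.648. In the 7 main classes the sums held from 2024370 UMIs (pericyte-like, QS) to 32968152 (endothelial-like, PF). The smallest sums of the further classes were 1096371 (border-associated macrophage-like, QS) and 1707364 (tanycyte-like, PF), so counting error is larger there.

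Alternatives set beforehand for cell shares were a minimum of 1000 UMIs, at most 10% mitochondrial UMIs, doublet calls kept, Leiden resolutions of 0.5 and 2, and variable genes centred per library. For expression and lists they were median-of-ratios size factors within the class, cells with at least 1000 UMIs, the mean over cells of CPM, free RNA subtracted at 5% of each class sum with the profile of the whole library, UMIs thinned to the smallest library (expression only) and list members with at least 200 UMIs (lists only). For carry-over they were a ratio of 1.5 to choose genes, a ratio above 1 in QS, and size factors. Added after seeing the data were analyses without clusters of low UMI counts, a minimum of 50 CPM and 30 UMIs for carry-over, and swapped PF parts. Also chosen then were which lists lead the report, the use of tanycyte-like and border-associated macrophage-like cells as further classes with at least 100 cells, list medians in single clusters with at least 100 cells per library, and the size of 0.3 (log2) at which opposite class medians were singled out. No class shift between size factors and class sums exceeded 0.1 on the log2 scale, the largest being -0.082 in tanycyte-like cells (HS/PF). Neuronal lists were left without values because no library held 200 neuron-like cells.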

Results

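Single-cell RNA sequencing was carried out on dissociated hypothalami of 8-week-old male mice to ask whether heat exposure leaves lasting differences in cell composition and in transcription. There was 1 library in each of 3 groups. PF mice were a control whose food intake was matched to that of the exposed mice, HS mice were heat-exposed, and QS mice were sampled in recovery after the exposure. The number of mice behind each library is not given in the sources used here, and mice of the RT condition were not analysed here. The files held 12836 barcodes and 100727912 UMIs (unique molecular identifiers, 1 per captured transcript) for PF, 12510 barcodes and 103891747 UMIs for HS, and 11720 barcodes and 93295920 UMIs for QS. After filtering, 11842, 11569 and 10772 cells remained, with medians of 6139.5, 6293 and 6159.5 UMIs per cell. With no replicate libraries, no difference could be set against the spread between animals. Values are therefore given with exact 95% intervals that cover counting error only, and higher and lower describe these libraries, not the conditions. HS against PF and QS against PF share the PF library, so anything particular to that library enters both.

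Endothelial-like cells, which line the vessels, were the most abundant class and made up 34.6% of PF, 33.8% of HS and 30.4% of QS cells. Microglia-like cells, the resident immune cells, made up 14.8%, 12.1% and 16.4%. Astrocyte-like cells were more frequent in HS (12.8%) and QS (13.8%) than in PF (9.33%), at 1.37 times (1.27 to 1.48) and 1.48 times (1.37 to 1.60) the PF share. Tanycyte-like cells, specialised cells of the floor of the third ventricle, made up 1.60% of PF (189 cells), 4.49% of HS (519 cells) and 3.27% of QS (352 cells). Their share was 2.81 times (2.38 to 3.34) the PF share in HS and 2.05 times (1.71 to 2.46) in QS. Oligodendrocyte-like cells, which make myelin, made up 7.55% in PF, 7.13% in HS and 10.9% in QS, 1.44 times (1.32 to 1.58) the PF share in QS.

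**Figure D1:**
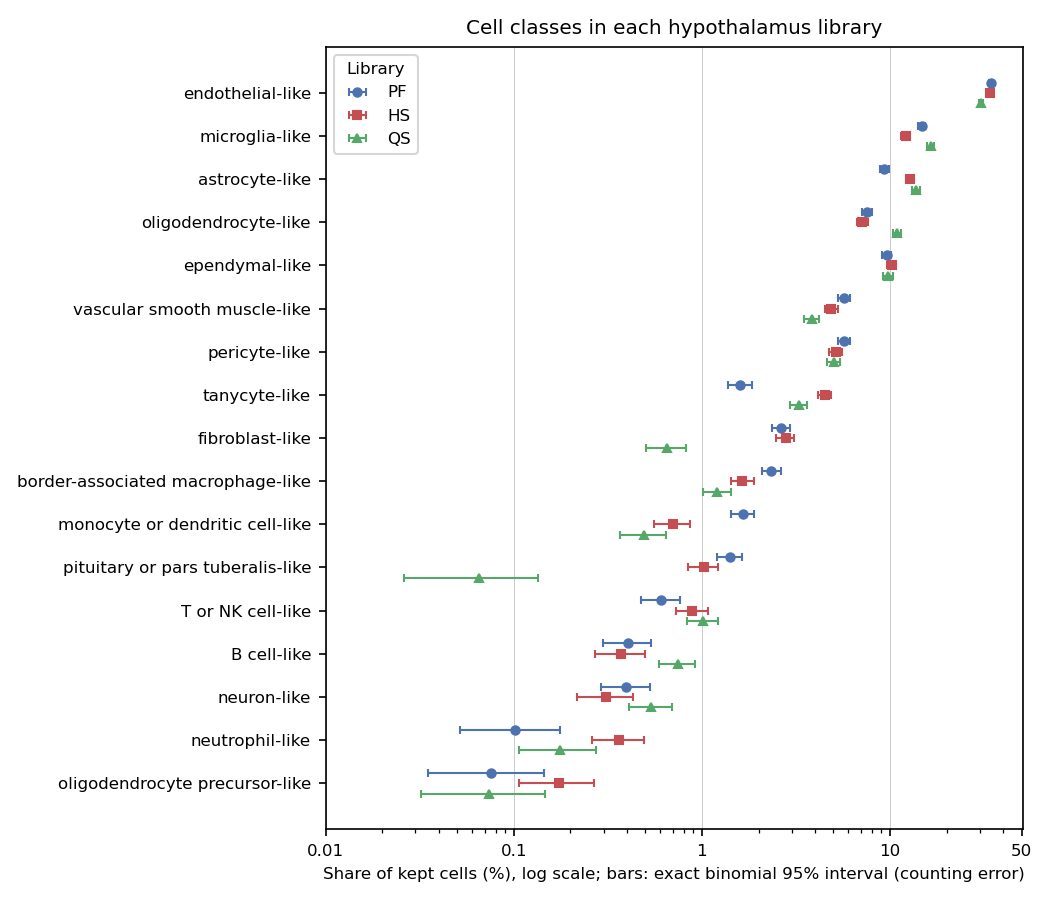
Share of kept cells in each of 17 named classes (vertical axis) as a percentage on a log scale (horizontal axis) for the PF, HS and QS libraries; bars are exact binomial 95% intervals of counting error. Tanycyte-like cells stand at 1.60% in PF against 4.49% in HS, and the QS points of fibroblast-like (0.650%) and pituitary or pars tuberalis-like cells (0.065%) lie to the left of the other libraries.

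Ependymal-like cells, the ciliated lining of the ventricles, had close shares of 9.61%, 10.2% and 9.77%. Pericyte-like cells made up 5.68%, 5.13% and 5.02%, and vascular smooth muscle-like cells 5.68%, 4.88% and 3.83%. Fibroblast-like cells, found in the meninges and around vessels, made up 2.63% of PF and 2.78% of HS but 0.650% of QS, a QS/PF ratio of 0.247 (0.188 to 0.322). Cells that resembled the pituitary or the pars tuberalis numbered 167 in PF, 118 in HS and 7 in QS, with shares of 1.41%, 1.02% and 0.065%. Their median UMIs were 1170 in PF, 12397 in HS and 607 in QS, and with at least 1000 UMIs per cell the HS/PF ratio went from 0.723 (0.566 to 0.921) to 1.13, so its direction rested on the UMI minimum.

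Among the blood-derived and border cells, monocyte or dendritic cell-like cells were less frequent in HS (0.7%) and QS (0.492%) than in PF (1.65%). Border-associated macrophage-like cells made up 2.34%, 1.64% and 1.21%. T or NK cell-like cells made up 0.608%, 0.890% and 1.01%, and B cell-like cells 0.405%, 0.372% and 0.743%. Neutrophil-like cells numbered 12, 42 and 19, with an HS/PF ratio of shares of 3.58 (1.85 to 7.48). Oligodendrocyte precursor-like cells numbered 9, 20 and 8. Of the 37 clusters, 3 stayed unnamed and held 1.57%, 1.25% and 1.68% of cells. These were cluster 27, led by the proliferation genes Mki67 and Top2a (0.996%, 0.692% and 0.241%), cluster 28 (0.566%, 0.536% and 0.873%) and cluster 35 (0.008%, 0.017% and 0.566%). Shares of cells from digested tissue also depend on how each hypothalamus was dissected and on which cells survived, and neither could be separated from group.

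Neuron-like cells were scarce, with 47 cells in PF, 36 in HS and 58 in QS (0.397%, 0.311% and 0.538%). This lies under the minimum of 200 cells per library, so none of the neuronal gene lists, which covered feeding and energy neuropeptides, hormone receptors, temperature-sensing channels and synaptic genes, was given a value. The cluster was led by the neuropeptide genes Vip and Avp. Avp (vasopressin) stood at 1390, 1877 and 1361 CPM (counts scaled to the UMI total of the class) in PF, HS and QS, and a single cell held 25.9%, 45.7% and 30.7% of its UMIs. Vip stood at 1480, 1436 and 2010 CPM, and a single cell held 25.9%, 17.9% and 22.4% of its UMIs.

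Most of the abundant transcripts differed little between the libraries. Over 7 classes with at least 200 cells in each library, and genes with at least 50 CPM in both libraries compared, the median size of the log2 ratio of CPM was 0.093 (0.091 to 0.094) for HS/PF, 0.1 (0.098 to 0.102) for QS/PF and 0.119 (0.117 to 0.12) for QS/HS, where counting error alone gave 0.040, 0.041 and 0.040. Random sets of cells from 1 library, each with about 0.5 of its cells and so fewer UMIs, differed by 0.037 and 0.036 in endothelial-like cells, where HS/PF stood at 0.085, but by 0.128 and 0.115 in pericyte-like cells, where HS/PF stood at 0.111. A ratio of at least 1.5 either way was reached by 126 of 25875 such pairs of a gene and a class for HS/PF (0.49%), 177 of 25687 for QS/PF (0.69%) and 405 of 25461 for QS/HS (1.59%). Among genes other than haemoglobin and the further kinds left out of naming, with at least 50 CPM in the library with more and 1 UMI in the other, 0 reached it the same way in all 6 of the largest classes in any comparison. A list member is called higher or lower where its ratio was at least 1.5 either way, its interval excluded 1 and the library with more held at least 30 of its UMIs.

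The comparison of HS with PF addressed heat exposure at matched intake. Genes that respond to glucocorticoids, the adrenal stress hormones, stood higher in HS. Zbtb16, a zinc-finger transcription factor (ENSMUSG00000066687, mm10 chromosome 9, 48654297 to 48836222), stood at 196 CPM in HS against 37.0 in PF endothelial-like cells, 5.30 times the PF level (4.99 to 5.64). The HS/PF ratio of Zbtb16 was 3.22 (2.80 to 3.72) in astrocyte-like, 4.09 (3.57 to 4.70) in oligodendrocyte-like and 12.1 (7.49 to 20.9) in pericyte-like cells. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), stood at 145 CPM in HS against 54.5 in PF microglia-like cells, a ratio of 2.66 (2.43 to 2.91). Sgk1, which encodes a serum and glucocorticoid-regulated kinase (ENSMUSG00000019970, chromosome 10, 21882184 to 21999903), stood at 755 against 229 CPM in oligodendrocyte-like cells, a ratio of 3.30 (3.12 to 3.49). Tsc22d3, a glucocorticoid-induced regulator (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), had ratios of 1.65 (1.60 to 1.69) in endothelial-like and 1.65 (1.55 to 1.77) in ependymal-like cells. Not every gene differed in every class: Sgk1 stood at 592 CPM in PF and 593 in HS endothelial-like cells, and Tsc22d3 had a ratio of 0.983 in pericyte-like cells. Over the 7 classes, 20 of 100 measured pairs of a list member and a class were higher in HS, 0 lower and 80 neither. The median log2 ratio of the list over classes was 0.19 (0.12 to 0.23), from 0.01 in vascular smooth muscle-like to 0.42 in oligodendrocyte-like cells, and 6 of 7 classes lay above the 95% range of 10000 random lists matched on expression.

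**Figure D2:**
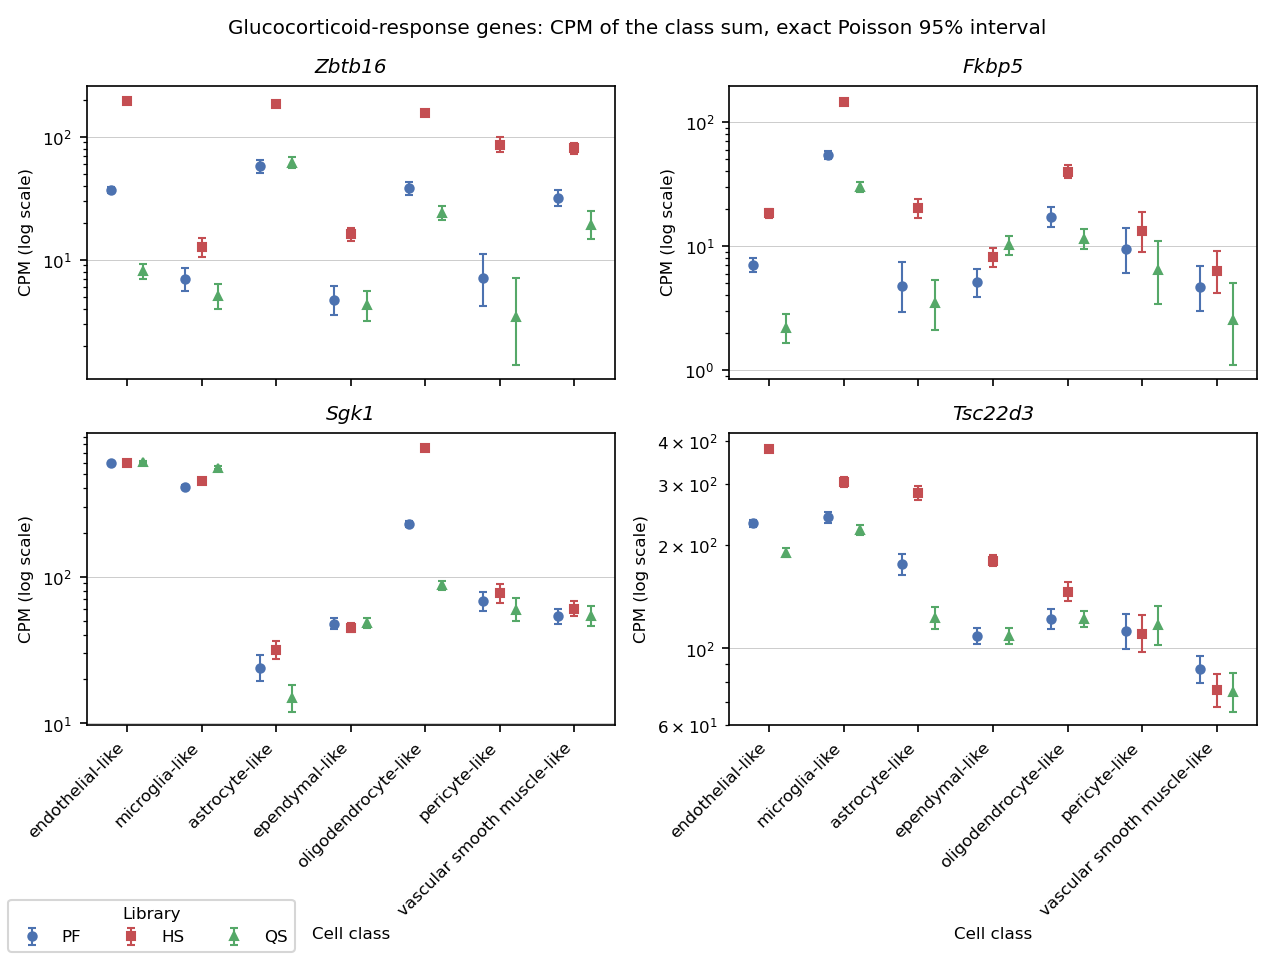
CPM on a log scale (vertical axis) of Zbtb16, Fkbp5, Sgk1 and Tsc22d3 in 7 cell classes (horizontal axis) for the PF, HS and QS libraries; bars are exact Poisson 95% intervals of counting error. Zbtb16 is highest in HS in every class shown, for example at 196 CPM in endothelial-like cells against 37.0 in PF and 8.12 in QS, while Sgk1 stands apart in HS mainly in oligodendrocyte-like cells.

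Heat shock and chaperone genes, which act in protein folding, were a little higher in HS. Their median log2 ratio was above 0 in 7 of 7 classes, with 0.24 (0.20 to 0.27) over classes, 0.06 in astrocyte-like and 0.33 in microglia-like cells. Few members reached the size set: 4 of 140 pairs were higher, 1 lower and 135 neither. Hsp90ab1, a cytosolic HSP90 gene (ENSMUSG00000023944, chromosome 17, 45567775 to 45573271), stood at 3837 against 2824 CPM in endothelial-like cells, a ratio of 1.36 (1.35 to 1.37). Hsph1 had a ratio of 1.55 (1.47 to 1.63) in microglia-like cells and Hspa1b, an inducible HSP70 gene with the near-identical copy Hspa1a, 1.65 (1.59 to 1.73) in vascular smooth muscle-like cells. Hspa1a in ependymal-like cells went the other way, at 316 CPM in HS against 495 in PF (0.637, 0.613 to 0.662). Genes of the endoplasmic reticulum stress response had a median of 0.10 (0.08 to 0.18), with 0 of 105 pairs higher, 2 lower and 103 neither. The cold-inducible RNA-binding list was below 0 in 7 of 7 classes, with a median of -0.21 (-0.24 to -0.15). Its member Cirbp, whose RNA is known to be more abundant at lower temperature (ENSMUSG00000045193, chromosome 10, 80165985 to 80172786), stood at 0.644 of the PF level (0.609 to 0.681) in endothelial-like cells and 0.601 (0.507 to 0.711) in pericyte-like cells.

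Antigen presentation genes were lower in HS in all 7 classes, with a median log2 ratio of -0.45 (-0.48 to -0.33) and with 0 of 91 pairs higher, 24 lower and 67 neither. In endothelial-like cells the immunoproteasome genes Psmb8 and Psmb9 stood at 0.681 (0.663 to 0.7) and 0.679 (0.656 to 0.703) of the PF level, at 258 and 171 CPM in HS, both under the size set. Class II genes of this list stood low in classes not known to make them, such as Cd74 at 27.2 CPM in PF and 13.4 in HS oligodendrocyte-like cells, and their main carriers, monocyte or dendritic cell-like and border-associated macrophage-like cells, were also less frequent in HS. The oligodendrocyte-like median of -0.19 turned to 0.10 with free RNA subtracted at 5% (antigen presentation in oligodendrocyte-like cells). Interferon-response genes were below 0 in 7 of 7 classes, at -0.37 (-0.41 to -0.27), with 1 of 119 pairs higher, 13 lower and 105 neither. Irf7, an interferon-induced transcription factor, stood at 0.635 (0.616 to 0.654) of the PF level in endothelial-like cells, and Ifi27l2a at 0.507 (0.448 to 0.574) in oligodendrocyte-like cells. Rsad2, an antiviral gene, went the other way in microglia-like cells, at 95.8 CPM in HS against 63.9 in PF.

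Cholesterol synthesis genes had a median of -0.17 (-0.25 to -0.11), below 0 in 7 of 7 classes, with 0 of 128 pairs higher, 9 lower and 119 neither. Insig1, which regulates sterol synthesis, stood at 0.584 (0.427 to 0.793) of the PF level in pericyte-like and 0.663 (0.567 to 0.775) in ependymal-like cells. Mitochondrially encoded transcripts had a median of -0.13 and nuclear oxidative phosphorylation genes of -0.07, and no member of either list reached the size set in any class. Immediate early genes, which report recent stimulation and can also be set off by dissociation, had 0 of 155 pairs higher and 0 lower, although the oligodendrocyte-like and ependymal-like medians were -0.39 and -0.32. The astrocyte-like median of immediate early genes, -0.08, became 0.14 with free RNA subtracted at 5%. Glycolysis genes had 5 of 130 pairs higher and 3 lower, and oxidative stress genes 1 of 114 higher and 0 lower. Circadian clock genes had 3 of 109 pairs higher and 7 lower, cytokine receptor genes 5 of 128 higher and 1 lower, and cell cycle genes 3 of 53 higher and 0 lower.

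Among the genes named by rank of ratio, Scgb3a1 stood at 2.0 times the PF level (1.91 to 2.10) in endothelial-like cells, the cyclin gene Ccnd3 at 2.0 (1.91 to 2.09) in microglia-like cells and Frmpd1 at 2.15 (1.98 to 2.34) in astrocyte-like cells. Map7d2 reached 2.03 (1.52 to 2.73) in pericyte-like cells and Ahsa2 1.58 (1.41 to 1.76) in ependymal-like cells. Vcam1, an adhesion molecule for leukocytes (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), stood at 378 CPM in HS against 634 in PF endothelial-like cells, a ratio of 0.596 (0.583 to 0.610). Dbp, a transcription factor of the clock output (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), stood at 0.370 (0.317 to 0.432) of the PF level in astrocyte-like and 0.469 (0.427 to 0.515) in ependymal-like cells. The noncoding transcript AY036118 was at 0.556 in endothelial-like and 0.482 in pericyte-like cells. The lowest ratios elsewhere were 0.663 for Lgals3bp and 0.683 for Rgs3 in microglia-like cells, 0.566 for Pfkfb4 in astrocyte-like cells, 0.657 for Acox3 in ependymal-like cells, and 0.697 for Rasal1 and 0.711 for Mthfsl in oligodendrocyte-like cells.

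The comparison of QS with PF asked which differences were present in recovery. The glucocorticoid list, higher in HS, was below the control in QS, at a median of -0.22 (-0.28 to -0.15) with 1 of 98 pairs higher, 16 lower and 81 neither. Its lowest class medians were -0.49 in astrocyte-like and -0.43 in oligodendrocyte-like cells, and the ependymal-like and vascular smooth muscle-like medians lay near 0 at 0.02 and 0.01. Zbtb16 stood at 8.12 CPM in QS endothelial-like cells, 0.219 (0.188 to 0.254) of the PF level. Fkbp5 stood at 0.550 (0.487 to 0.621) in microglia-like, Sgk1 at 0.382 (0.352 to 0.415) in oligodendrocyte-like, Cdkn1a at 0.532 (0.421 to 0.670) and Per1 at 0.584 in astrocyte-like cells. Zbtb16 in astrocyte-like cells was near the PF level (1.07, 0.909 to 1.27), Fkbp5 in ependymal-like cells was the 1 member called higher, at 10.2 CPM against 5.09, and Sgk1 in microglia-like cells stood at 1.35 times the PF level.

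Antigen presentation genes were again below PF in 7 of 7 classes, at -0.48 (-0.67 to -0.46), with 0 of 90 pairs higher, 41 lower and 49 neither. In endothelial-like cells H2-Aa and Cd74 stood at 0.22 (0.178 to 0.269) and 0.251 (0.223 to 0.282) of the PF level, from 20.3 and 55 CPM in PF, while monocyte or dendritic cell-like and border-associated macrophage-like cells were at 0.299 and 0.516 of their PF shares. With free RNA subtracted at 5%, the oligodendrocyte-like medians moved from -1.07 to -4.22 for antigen presentation and from -0.58 to -1.85 for the interferon response. Counts were cut at 0 in this setting, so medians under it can rest on small remainders. Their size, here and further on, does not measure a larger decrease. Interferon-response genes were below 0 in 6 of 7 classes, with 11 of 119 pairs higher, 29 lower and 79 neither. Irf7 stood at 0.297 of the PF level in pericyte-like cells, Ifitm3 at 0.388 in microglia-like cells and Ifi27l2a at 0.208 (0.179 to 0.241) in oligodendrocyte-like cells. Ependymal-like cells were the exception, with a median of 0.47 and 8 of 17 members higher and 1 lower. There Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731) stood at 132 CPM in QS against 42.5 in PF, a ratio of 3.11 (2.81 to 3.45). The chemokine gene Cxcl10 had a ratio of 2.87 (2.59 to 3.17) and Isg15 of 2.79 (2.47 to 3.15) in these cells.

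Immediate early genes also differed by class, with a QS/PF median of 0.46 in ependymal-like and -0.61 in oligodendrocyte-like cells. In ependymal-like cells Arc, an activity-induced gene, stood at 82.3 against 40.7 CPM (2.02, 1.81 to 2.26) and Nr4a1 at 335 against 193. In oligodendrocyte-like cells 14 of 22 members were lower, among them Fosb at 0.484 (0.449 to 0.522) and Ier2 at 0.522 of the PF level. With free RNA subtracted at 5%, the median of immediate early genes was -1.21 in oligodendrocyte-like cells and went from -0.45 to -1.15 in astrocyte-like cells. Cholesterol synthesis genes were at 0.40 in ependymal-like cells, where 6 of 19 members were higher, among them Idi1 at 1.89 (1.65 to 2.16) times the PF level. Over all 7 classes that list had 7 of 128 pairs higher and 0 lower. Heat shock genes went both ways around a median over classes of -0.02 (-0.05 to 0.01), from -0.30 (-0.35 to -0.21) in astrocyte-like to 0.21 (0.17 to 0.27) in vascular smooth muscle-like and 0.23 (0.18 to 0.26) in ependymal-like cells, with 0 of 140 pairs higher and 7 lower. The cold-inducible list was at 0.03 with 0 of 35 pairs higher or lower. Mitochondrially encoded transcripts were below 0 in 7 of 7 classes, at -0.21 (-0.21 to -0.16), with 7 of 91 pairs lower. Nuclear oxidative phosphorylation genes stood at -0.48 in astrocyte-like cells, where 5 of 25 members were lower, including Ndufa1 at 0.546 (0.424 to 0.701). The mix of astrocyte-like clusters differed between PF and QS, and this list was not measured within single clusters. Endoplasmic reticulum stress genes had 2 of 106 pairs higher and 0 lower, glycolysis genes 1 of 129 higher and 4 lower, oxidative stress genes 3 of 112 higher and 3 lower, and clock genes 5 of 109 higher and 5 lower. Haemoglobin transcripts, which come from red blood cells, went in opposite directions, from -3.21 in astrocyte-like to 5.03 in vascular smooth muscle-like cells, with 20 of 28 pairs higher and 6 lower. They were higher in QS than in HS in 28 of 28 pairs, and in HS/PF 0 of 24 were higher and 8 lower. With the mean over cells these haemoglobin medians were -1.88 in astrocyte-like and 3.22 in vascular smooth muscle-like cells.

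**Figure D3:**
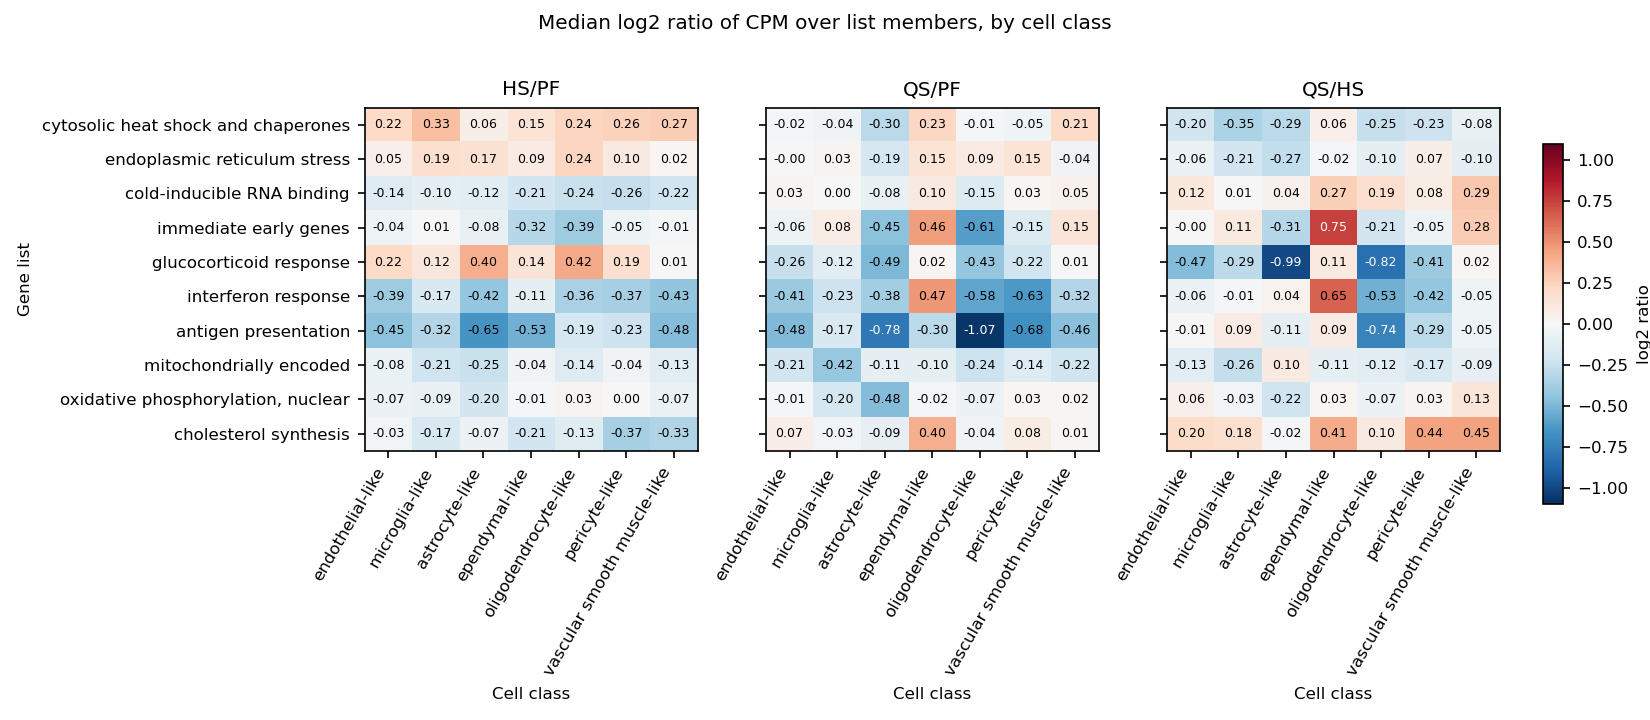
Median log2 ratio of CPM over the measured members of 10 gene lists (vertical axis) in 7 cell classes (horizontal axis) for HS/PF, QS/PF and QS/HS, with colour and printed value giving the same number. The glucocorticoid list is positive in HS/PF (0.42 in oligodendrocyte-like cells) and negative in most classes of QS/HS, and the interferon list is positive in ependymal-like cells in QS/PF (0.47).

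By rank of ratio, the histone gene Hist1h1c stood at 1.73 (1.64 to 1.83) and Ddc, which encodes aromatic amino acid decarboxylase, at 1.72 (1.64 to 1.81) times the PF level in QS endothelial-like cells. Microglia-like cells were led by Fam71a at 2.09 (1.85 to 2.36) and the interferon-induced Ifit1 at 1.81 (1.70 to 1.92). Egfem1 (1.61) and Pde1c (1.51) led astrocyte-like cells, Ifit3b (3.28) and Ifit3 ependymal-like cells, Adamts6 (1.53) and Cdh10 (1.49) oligodendrocyte-like cells, and Dmtf1 (1.92) and Rab24 (1.79) pericyte-like cells. At the low end, Ccnd3 stood at 0.580 in microglia-like cells and the metallothionein Mt3 at 0.584 (0.558 to 0.612) in astrocyte-like cells. Slc15a2 (0.628) and Kirrel3 (0.678) were lowest in ependymal-like cells, Hopx (0.552) followed Sgk1 in oligodendrocyte-like cells, and Fosl2 (0.506) and Irf1 (0.534) were lowest in pericyte-like cells. Plvap, a gene of fenestrated endothelium (ENSMUSG00000034845, chromosome 8, 71497765 to 71511752), stood at 4.14 CPM in QS against 63.6 in PF endothelial-like cells. Its carrier, the Plvap-led endothelial cluster 30, held 72 cells in PF, 92 in HS and 5 in QS.

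The comparison of QS with HS set recovery against exposure. The glucocorticoid list stood lower in QS, with a median of -0.41 (-0.49 to -0.32), 1 of 100 pairs higher, 39 lower and 60 neither. In astrocyte-like cells 12 of 14 members were lower and in oligodendrocyte-like cells 10 of 15. The QS/HS ratio of Zbtb16 was 0.0413 (0.0358 to 0.0475) in endothelial-like, 0.333 in astrocyte-like, 0.155 in oligodendrocyte-like and 0.0401 (0.0159 to 0.0842) in pericyte-like cells. That of Fkbp5 was 0.207 (0.185 to 0.231) in microglia-like cells and that of Sgk1 0.116 (0.108 to 0.125) in oligodendrocyte-like cells. Heat shock genes were at -0.23 (-0.27 to -0.19), with 3 of 140 pairs higher and 13 lower, and the cold-inducible list was above 0 in 7 of 7 classes at 0.12 (0.09 to 0.20), with 4 of 35 pairs higher. Cirbp stood at 1.95 times the HS level in endothelial-like and 2.18 times in pericyte-like cells.

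Cholesterol synthesis genes were higher in QS than in HS in 19 of 127 pairs and lower in 0, at a median of 0.20 (0.14 to 0.35). Insig1 stood at 2.30 times (1.99 to 2.65) the HS level in ependymal-like cells. Interferon and antigen presentation lists lay near 0 over classes in QS/HS, at -0.05 each, unlike their values against PF. The interferon list had 14 of 118 pairs higher and 13 lower, with ependymal-like cells at 0.65 and oligodendrocyte-like cells at -0.53. The antigen presentation list had 16 of 86 pairs lower, 8 of them in oligodendrocyte-like cells. With free RNA subtracted at 5%, the oligodendrocyte-like medians were -1.41 for the interferon response and -3.66 for antigen presentation. In ependymal-like cells 18 of 23 immediate early genes were higher, at a median of 0.75, including Arc at 2.77 (2.47 to 3.1) and Atf3 at 1.97 times the HS level, and in astrocyte-like cells the median was -0.31. For astrocyte-like cells the same list of immediate early genes stood at -1.22 with free RNA subtracted at 5%.

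By rank of ratio in QS/HS, Hist1h1c (2.15, 2.03 to 2.29) and Ndnf (2.14, 2.05 to 2.23) led endothelial-like cells, where Zbtb16 and Plvap (0.0718) were lowest. Ifit1 (1.85) and Ifnb1, the interferon beta gene (1.73, 1.64 to 1.82), led microglia-like cells, with Ccnd3 at 0.291. In astrocyte-like cells Mir9-3hg (1.95) and the homeobox gene Nkx2-2 (1.86) were highest. Ependymal-like cells had Ifit3 at 3.72 and Ifit3b at 3.08, against Rnf144b at 0.570 and Tspan9 at 0.6. Gfra1 and Synpr both stood at 1.94 in oligodendrocyte-like cells. In pericyte-like cells AY036118 stood at 2.21 and Mpp2 at 0.461.

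Whether the HS difference was still seen in QS was measured with the PF cells of each class split at random, so that HS and QS were set against different PF cells. Of 984 pairs of a gene and a class at least 2-fold higher in HS, 227 were at least 1.5-fold higher in QS, 23.1% (20.5 to 25.8). Simulated libraries with no difference, which held counting error only, gave 20.8% (17.1 to 24.8). Of 1332 pairs lower in HS, 426 were lower in QS, 31.98% (29.5 to 34.6), against a simulated 21.6% (18.2 to 25.3). With a minimum of 50 CPM and 30 UMIs, added after seeing the data, 0 of 21 pairs higher in HS were also higher in QS. The exact interval reaches 16.1%, but it treats pairs as independent although some genes recur across classes, so it is too narrow. Of 16 lower pairs, 5 were also lower. The 21 pairs included Zbtb16 in 5 classes, Fkbp5 and Ccnd3 in microglia-like cells and Sgk1 in oligodendrocyte-like cells. Another 6 of them were Gh, the growth hormone gene of pituitary cells, at 78.8 CPM in HS endothelial-like cells. There PF had 0 UMIs of 32968152 and QS 0 of 25132750, which allow up to 0.091 and 0.119 CPM, and Gh led the pituitary or pars tuberalis-like cluster. With 0 UMIs in PF and QS, Gh had no QS ratio, so these 6 pairs could not count as higher in QS. How much pituitary tissue each dissection held is not known, which limits what Gh and the share of pituitary or pars tuberalis-like cells mean. The 5 lower pairs were Ifi27l2a in oligodendrocyte-like cells and Meis2, Ctnna2, Nav3 and Mbp in pericyte-like cells. Mbp is a myelin gene, and the rule that keeps free RNA out of the genes named by rank was not applied here. HS and QS were both set against cells of the PF library, so free RNA in PF was not excluded as the source.

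Microglia-like cells kept their homeostatic genes at close levels, with medians of 0.02 in HS/PF, 0.12 in QS/PF and 0.08 in QS/HS and 0 of 13 members higher or lower in each. The list of inflammatory cytokines and NF-kB targets stood at -0.07 in HS/PF, 0.24 (0.16 to 0.28) in QS/PF and 0.29 (0.24 to 0.35) in QS/HS, with 1 of 20 members higher in QS/PF and 3 in QS/HS. The chemokine gene Ccl3 stood at 2200 CPM in QS against 1384 in PF, a ratio of 1.59 (1.56 to 1.62), and Tnf at 867 against 610. Il1b was lower in HS, at 56.8 against 89.9 CPM. Cluster 7, led by Il1a, Ccl4, Tnf and Ifnb1, held 39.8% of microglia-like cells in PF, 37.6% in HS and 45.3% in QS. Disease-associated genes were at 0.10, 0.11 and -0.05, with Cst7 at 1.84 and Lgals3 at 1.60 times the PF level in HS and Axl at 0.651 in QS. The mean over cells in place of the sum turned the sign of the disease-associated microglia list in HS/PF, to -0.03, and in QS/HS, to 0.01.

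Endothelial-like cells had 15 blood-brain barrier genes near the PF level in HS, at 0.02 with 0 members higher or lower, and at 0.16 (0.13 to 0.18) in QS. The transferrin receptor gene Tfrc stood at 1.64 times (1.59 to 1.68) the PF level in QS and the lipid transporter Mfsd2a at 1.44. Endothelial activation genes were at -0.07 in HS/PF, where Vcam1 and Selp (0.469) were lower and the interleukin-1 receptor gene Il1r1 (1.67, 1.61 to 1.73) higher. In QS/PF they stood at -0.62 (-0.65 to -0.58) with 9 of 16 lower, among them Selp at 0.0694, Ackr1 at 0.336 and Ch25h at 0.323 (0.292 to 0.357). Several of these genes define cluster 11, led by Lcn2, Ackr1, Lrg1 and Vwf, which held 538 cells in PF, 507 in HS and 254 in QS. Within cluster 11 the QS/PF median of the activation list was -0.51 (-0.56 to -0.48), and within endothelial clusters 0, 1 and 5 it was -0.39, -0.36 and -0.16.

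In astrocyte-like cells the 13 homeostasis genes stood at -0.01, -0.07 and -0.10 in HS/PF, QS/PF and QS/HS with 0 members higher or lower, and the QS/PF value turned to 0.01 with size factors (astrocyte homeostasis). Reactive astrocyte genes were at -0.16, -0.16 and -0.29, with Lcn2 at 0.134 of the PF level in QS. Lcn2 also led endothelial cluster 11, which held 538 cells in PF and 254 in QS, so free RNA from those cells was not excluded. Cluster 8 held 54.8% of astrocyte-like cells in PF, and cluster 4 held 64.1% in HS and 56.7% in QS. Values of this class therefore compare different mixes of clusters. Immediate early genes in HS/PF, with a negative class median, stood at 0.063 in cluster 4 and 0.0 in cluster 8. The glucocorticoid list in QS/PF stayed negative in both, at -0.312 and -0.636. Among fibroblast-like cells, cluster 19 held 66.6% in PF and 67.1% in HS, and cluster 25 held 80.0% in QS. The 14 myelin genes of oligodendrocyte-like cells stood at 0.01, 0.10 and 0.10 with 0 members higher or lower, and Mobp was at 1.23 times the PF level in HS.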

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

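The tests of free RNA, of the time of day and of border tissue were chosen only after the results they measure were seen. The bounds of the others were written before their outcomes, but after the patterns they address had been seen. The use of list medians in single clusters, on which both tests of cluster mix rest, was also chosen after seeing the data. The class differences given here were not tested, since each group had 1 library.

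For the first pattern weighed, the glucocorticoid list higher in HS and lower in QS, a different cluster mix within classes could be the cause, but 13 of 18 clusters with at least 100 cells per library had a QS/HS median below -0.1 (12 with their whole interval), and the 5 others (ependymal-like 6, 14 and 18, vascular smooth muscle-like 9, pericyte-like 20) reached at most 0.06. Free RNA shared by all droplets adds CPM that depends on how many UMIs the cells of a class hold, and the test allowed a factor of 4. Gh in HS, for example, stood at 32.5 CPM in vascular smooth muscle-like and 81.3 in oligodendrocyte-like cells. Yet in the 5 classes with the list lower in QS, 10 of 15 members had an added CPM (HS over QS) beyond that factor. For these the lower bound in the highest class exceeded 4 times the upper bound in the lowest, as for Zbtb16 (188 in endothelial-like, 7.60 in microglia-like cells). In 3 of the 10 (Sgk1, Cdkn1a, Errfi1) the upper bound of the lowest class lay below 0, for Tsc22d3 only the estimate did (-6.60, upper bound 13.5), and free RNA stays open for the other 5 members. The time of day of collection stays open: only 1 of 8 clock genes (Dbp) moved one way in at least 6 of 7 classes by 0.5 or more in QS/HS, but the bound of fewer than 2 was too lax, because Dbp was higher in QS in 7 of 7 classes (median 0.78), Nr1d1 was lower in HS than PF in 7 of 7 (-0.51), glucocorticoids follow a daily rhythm, and the collection time is not given. A difference in stress hormone between heat exposure and recovery is a biological explanation that was not tested.

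The second pattern is that pituitary or pars tuberalis-like cells, fibroblast cluster 19 and the fenestrated endothelial cluster 30 were all scarce in QS, with QS/HS share ratios of 0.064 (0.025 to 0.135), 0.070 (0.037 to 0.119) and 0.058 (0.019 to 0.141), so in 3 of 3 groups the upper bound lay below 0.5, as less border tissue in the QS dissection would give; more pituitary tissue in HS, the only library with Gh UMIs in the 7 main classes, stays open for the first, which was also low against PF (0.046, 0.018 to 0.097). These 3 groups were picked because they were low, so this test cannot support that explanation, and border cells not picked that way, fibroblast cluster 25 (0.567, 0.403 to 0.792) and border-associated macrophage-like cells (0.735, 0.583 to 0.923), were less reduced. Tanycyte-like cells of the ventricle floor stood at 0.728 (0.634 to 0.836) of the HS share but at 2.05 (1.71 to 2.46) times the PF share, which less basal tissue in QS would not give, and endothelial cluster 11 stood at 0.538 (0.461 to 0.627) of the HS share. Loss through filters or doublet calls was not settled by the bounds set beforehand. Removed QS barcodes with at least 3 markers made up 30% of the gap of 363 cells, above the bound of 20% but short of the whole gap. By a comparison that those bounds did not include, HS lost 192 such barcodes (52.9%) and PF 244 (67.2%), more than the 109 of QS. Putting them back would therefore not close the gap. Relative to the kept cells named as these classes (478 in PF, 440 in HS and 77 in QS), QS lost the most. The marker rule is wider than those names, however, so these counts are not like for like. Barcodes with at least 3 fibroblast markers numbered 1267, 1212 and 528 among those kept in PF, HS and QS. Among those removed they numbered 240, 179 and 109. Dissection and a true loss of these cells in recovery cannot be told apart, as each group has 1 library.

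The third pattern is the interferon list, higher in QS than PF in ependymal-like cells and lower in 6 other classes. A few cells with very high counts could carry it, but without the 5% of cells with most list UMIs the median was 0.45 (0.33 to 0.591) against 0.47. RNA from microglia was argued against by 8 microglial genes, whose median in ependymal-like cells was -0.793 (-0.902 to -0.709). Cluster mix within the class was argued against as the whole cause by 2 of 3 ependymal-like clusters at 0.54 and 0.46, although cluster 18 stood at -0.29. Cluster 6 (0.54) stood at -0.225 in HS/PF and 0.79 (0.737 to 1.015) in QS/HS. Cluster 14 (0.46) was already above PF in HS, at 0.279 (0.123 to 0.459), and close to HS in QS, at 0.067 (-0.014 to 0.235). Tanycyte-like cells, a further class, stood at 0.136 (0.032 to 0.323) in QS/PF and -0.222 in QS/HS. An interferon response of ventricular cells in recovery stays a hypothesis found and tested on the same data, and a difference in how the tissue was handled was not tested.

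Other differences between classes were large. Interferon-response medians differed by 1.104 in QS/PF between ependymal-like (0.47) and pericyte-like cells (-0.63). In QS/HS they differed by 1.18 between ependymal-like (0.65) and oligodendrocyte-like cells (-0.53). Immediate early gene medians differed by 1.071 in QS/PF between ependymal-like (0.46) and oligodendrocyte-like cells (-0.61). In QS/HS they differed by 1.062 between ependymal-like (0.75) and astrocyte-like cells (-0.31). Haemoglobin medians differed by 8.241 in QS/PF between vascular smooth muscle-like (5.03) and astrocyte-like cells (-3.21), with Hbb-bs at 350 against 13.95 CPM in the former and 85.4 against 516 CPM in the latter.

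Of the signals in cells that carry no name, cluster 28, led by 9630013A20Rik, Tmem163 and Nfasc, held 67, 62 and 94 cells in PF, HS and QS, a QS/PF share ratio of 1.542 (1.12 to 2.14). Cluster 35 held 1, 2 and 61 cells, a ratio of 67.059 (11.6 to 2691.57). Its QS cells carried the endothelial gene Cldn5 at 2110 CPM together with the ependymal gene Ccdc153 at 603.9 CPM, which stood at 5.76 CPM in QS endothelial cluster 11.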

How the results depend on the processing

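The analyses without clusters of low UMI counts, with 50 CPM and 30 UMIs for carry-over, and with swapped PF parts were tests chosen only after the results were seen. Of 226 alternatives for shares, 224 lay within the main interval. So did 285 of 306 for lists over classes, 2022 of 2163 for lists in one class and 965 of 1039 for genes in one class. For the median size of log2 ratio 5 of 15 did, and for carry-over 5 of 10. A turn of direction was counted only where the main interval excluded no difference, and by that rule no gene turned. For the values here the cause was not tested. Depth limits border-associated macrophage-like cells most, and pericyte-like cells most among the 7 main classes. No paired analysis was possible because each group had 1 library.

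For shares, oligodendrocyte QS/PF became 1.58 with at most 10% mitochondrial UMIs, and pituitary or pars tuberalis HS/PF turned to 1.125 with at least 1000 UMIs per cell. The median size of log2 ratio (HS/PF, QS/PF, QS/HS) became 0.103, 0.11 and 0.126 with the mean over cells, 0.095, 0.104 and 0.123 with free RNA subtracted, 0.095, 0.103 and 0.122 with thinned UMIs, and 0.103 (QS/PF) with size factors. With free RNA subtracted, over classes in HS/PF, immediate early genes stood at -0.04 and antigen presentation at -0.318; immediate early genes in astrocyte turned to 0.14 and antigen presentation in oligodendrocyte to 0.095. With the mean over cells, immediate early genes stood at -0.171 (QS/PF) and -0.069 (QS/HS), glucocorticoid response at -0.502 (QS/HS) and antigen presentation at -0.451 (QS/PF), and disease-associated microglia turned to -0.027 (HS/PF) and 0.013 (QS/HS). With members of at least 200 UMIs, antigen presentation stood at -0.321 (HS/PF) and -0.311 (QS/PF), and cell cycle in endothelial turned to 0.051 (QS/HS). Size factors turned astrocyte homeostasis to 0.006 (QS/PF), and leaving out clusters of low UMI counts turned haemoglobin in endothelial to 0.005 (HS/PF). Carry-over of genes higher in HS became 16.17% with a ratio of at least 1.5 to choose genes, 48.17% with a ratio above 1 in QS and 0.0% with at least 50 CPM and 30 UMIs, and of genes lower in HS 25.01% and 55.03% with the first 2 of these. No simulation without a difference was run for those 2 settings. Many pairs would pass a ratio above 1 with no difference, so the larger shares under it do not show more carry-over.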

Other observations

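The use of tanycyte-like and border-associated macrophage-like cells as further classes was chosen only after the data were seen, and no tests were run on them.

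Tanycyte-like cells, which sense nutrients and hormones at the floor of the third ventricle, showed immediate early genes at a median log2 ratio of 0.79 in HS/PF and 0.90 in QS/PF, with 15 and 18 of 21 members higher. Fos, an activity-induced transcription factor, stood at 2543 CPM in PF, 4919 in HS and 5872 in QS. Junb stood at 932, 1954 and 1913 CPM, and Ier2 at 429, 1013 and 922 CPM. Glucocorticoid-response genes were at 0.39 in HS/PF, with 4 members higher, and at 0.06 in QS/PF. Zbtb16 stood at 24.0, 103 and 20.7 CPM and Fkbp5 at 63.8, 146 and 50.3 CPM. Interferon-response genes were at 0.37 in HS/PF, unlike the 7 larger classes, with 5 members higher, among them Ifit3 at 141, 327 and 235 CPM. Cxcl10 stood at 167, 563 and 570 CPM. Cholesterol synthesis genes were at -0.45 in HS/PF with 4 members lower. The list of tanycyte function and thyroid hormone was near 0, at -0.06 in HS/PF and 0.14 in QS/PF. Within it, Dio2, which makes active thyroid hormone, stood at 61.5 CPM in PF and 117 in HS (1.91, 1.55 to 2.37), and the thyroid hormone transporter Slco1c1 at 67.4 and 33.9. Dio3, which inactivates the hormone, stood at 7.03 CPM in PF and 24.5 in QS (3.48, 1.87 to 7.05).

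Border-associated macrophage-like cells, the macrophages of meninges and vessels, had antigen presentation genes at -0.31 in HS/PF and -0.46 in QS/PF, with 6 members lower in the latter. Cd74 stood at 1895, 1325 and 1239 CPM in PF, HS and QS. Cholesterol synthesis genes were at -0.84 in HS/PF and -0.48 in QS/PF, with 4 members lower in each. Glucocorticoid-response genes were at 0.24 in HS/PF, 0.05 in QS/PF and -0.02 (-0.17 to 0.12) in QS/HS, where 2 of 13 members were lower and 11 neither. Members went apart in QS, with Fkbp5 at 47.9, 188 and 17.3 CPM and Sgk1 at 96.7, 101 and 130 CPM. Haemoglobin transcripts were at -6.36 in HS/PF and -5.09 in QS/PF with 4 of 4 members lower in each, and Hbb-bs stood at 773, 8.65 and 27.4 CPM, so the PF cells of this class carried more of these transcripts.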
